A study of Mus musculus with 10 samples.

How the data were processed

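RNA from the periotic tissue of mouse embryos at embryonic day 12.5 was measured on Affymetrix Mouse Gene ST 1.0 arrays, 1 embryo per array. Periotic tissue here is the otic vesicle, the epithelial sac that forms the inner ear, with the mesenchyme around it. Per the labels, left and right tissue of an embryo was pooled, RNA was extracted with a column kit, and biotin-labelled cRNA was made from 300 ng of total RNA. The 5 mutants carried a conditional knockout of Tbx1 driven by T-Cre, a recombinase active in the early mesoderm. The 5 controls were T-Cre conditional heterozygotes. The labels call the samples biological replicates.

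The deposited values are on the log2 scale, and the authors made them with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects the background, sets all arrays to 1 distribution and summarises the probes of each probe set. The log2 scale is read from the values, whose array medians lay between 6.19 and 6.27. The probe file version behind the summary is not given in the sources used here. An array has no read depth, and the number of arrays limits the precision.

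The table held 35557 probe sets. The platform annotation listed 23410 of them with a gene, 21789 with 1 gene symbol and 1621 with several, and 12147 were not listed. Gene ids matched 21698 of the 21789 to the RefSeq gene table of assembly GRCm38.p6, and 91 kept the annotation's name. That table served only for names and for which genes neighbour each other. All 21789 probe sets with 1 symbol were tested, and each of 19938 genes was read from its probe set with the highest mean over the 10 arrays.

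Mutants and controls were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over the 21789 probe sets and a threshold of 0.05. Intervals are at the 95% level. Single values were also compared by exact two-sided permutation of the 10 arrays, whose smallest possible p is 0.00794. The samples, the design, the alternatives and 547 genes in lists were fixed before the data were examined. Of these genes, 507 were measured. The 25 lists other than the sex-linked markers were tested with limma's camera at its preset inter-gene correlation of 0.01, with adjustment over the 25. Camera with an estimated correlation and fry were also run. Fry's directional test asks whether the genes of a list move one way on balance, and its mixed test whether they change in either direction.

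The genes named are Tbx1, then the 10 largest changes in each direction among genes past the threshold whose groups did not overlap. Where fewer than 10 passed, places were filled by the smallest p among genes without overlap, and these are said to miss the threshold. Each list gave its members past the threshold, at most 6, or otherwise its 2 members of smallest p. Cyp26a1, Cyp26b1, Cyp26c1 and Pou3f4 were always included. Predicted and RIKEN-type genes were counted but not named. Members that passed when adjusted over the list alone, and further members printed with them, were added after their values were seen.

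The replicate numbers of the labels were checked for pairing. Deviations from the group means correlated at 0.122 to 0.247 between a mutant and the control of the same number and at -0.392 to 0.382 between other numbers. Every same-number correlation was above 0.1, so the numbers were taken to pair the arrays, although only 2 of the 5 mutants correlated best with their own number. The labels do not say what a number shares. The main limma fit, the exact permutations and the 100 splits treat the arrays as unpaired, so their p-values and counts take no account of the pairs. Immediate early genes split the arrays into those numbered 1 to 3 and those numbered 4 and 5 in both groups, and this split is called the array batch. Within a batch some other numbers correlated about as highly, such as mutant 1 with control 2 (0.169) and mutant 5 with control 4 (0.382). Others did not, such as mutant 2 with control 3 (-0.045). The batch may thus account for the same-number correlations, and counts over same-number pairs rest on a pairing that is assumed. The sex of each embryo was read from Xist and 3 Y-linked genes.

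The fit was tested on simulated data with 21789 probe sets at the measured means and spreads, for the comparison of mutants with controls. It recovered 80 of 100 probe sets changed by 0.5 on the log2 scale and 95 of 100 changed by 1, with 16 false calls among 191. With no change simulated it made 0 calls. A list shifted by 0.25 was called, 1 of 25. The simulated genes were independent, so the simulation says nothing about genes that vary together. With so many true changes the adjusted threshold is easier to pass than in the real comparison, which called 2 genes. The recovered shares therefore do not give the chance of finding a change of that size in the real data.

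The alternatives were eBayes without the trend and robust, a further quantile normalization, centring on array medians, only probe sets at or above the median mean signal, array weights, sex in the fit, the replicate number as a block, each array left out, a fold threshold of 1.5, treat against a fold of 1.2, and all probe sets. Fits by array batch, without mutants 4 and 5, with the neural lists as a term, and permutation of list means were added after seeing the data. Probe sets with several symbols were left out of all named results.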

Results

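The series asks how loss of Tbx1, a T-box transcription factor, from the mesoderm alters gene expression in the developing ear. It holds 10 arrays of periotic tissue at embryonic day 12.5, from 5 mutant and 5 control embryos. The arrays correlated at 0.984 to 0.996 with each other. Xist and Y-linked genes showed 1 male and 4 female mutants and 2 male and 3 female controls.

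Tbx1 was lower in the mutants. Its log2 signal (probe set 10438347) was 7.83 ± 0.36 (SD, n = 5) in the mutants and 8.71 ± 0.31 (SD, n = 5) in the controls, and the exact permutation p was 0.0159. The log2 difference was -0.88 with a standard error of 0.17, which left 54.2% of the control signal (95% interval 41.8 to 70.3%). In 4 of the 5 mutants the signal lay below the lowest control. The limma adjusted p of Tbx1 over all probe sets was 0.452, and 0.0849 with the replicate number as a block, so Tbx1 missed the threshold in both. Adjusted over the list alone, Tbx1 was the 1 of 15 T-box factors that passed. The difference was -0.93 in the arrays numbered 1 to 3 and -0.81 in those numbered 4 and 5. The part of Tbx1 that the probe set reads relative to the deleted part is not given in the sources used here, and the otic epithelium and the heterozygous controls keep Tbx1 alleles.

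Nr1h5 rose in the mutants and the signal of Sycp1 was higher, and no other gene passed the threshold in either direction. Nr1h5, a nuclear receptor of the farnesoid X receptor family (probe set 10500780), had a log2 signal of 3.94 ± 0.15 (SD, n = 5) in the controls and 5.64 ± 0.25 (SD, n = 5) in the mutants. The measured log2 difference of Nr1h5 by limma was 1.69 with a standard error of 0.12 and an adjusted p of 4.57e-05. Sycp1, a component of the meiotic synaptonemal complex (probe set 10500754), read 3.06 ± 0.09 in the controls and 3.84 ± 0.14 in the mutants (SD, n = 5 each), with a limma adjusted p of 0.00156. All 5 mutants lay above all 5 controls for each gene. No measured gene lies between Nr1h5 and Sycp1 in the gene order of GRCm38.p6. Y-linked probe sets in the female embryos, which serve here as a measure of background, read 3.12 to 4.36. No array read Sycp1 above 4.36, so no fold or log2 difference is given for it, whereas Nr1h5 exceeded 4.36 in the 5 mutants and in 0 of the controls. With the controls set to that background value, the mean of Nr1h5 was 2.43-fold higher in the mutants, an estimate without an interval. Within the arrays numbered 1 to 3 the measured Nr1h5 difference was 1.76 (interval 1.46 to 2.06), and within those numbered 4 and 5 it was 1.60 (1.26 to 1.94). With the controls set to the background value, the lower interval bound of the difference was 0.75 or more in each batch, using the standard error of the values as measured. With 4 arrays in the latter batch, 0 genes passed.

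**Figure D1:**
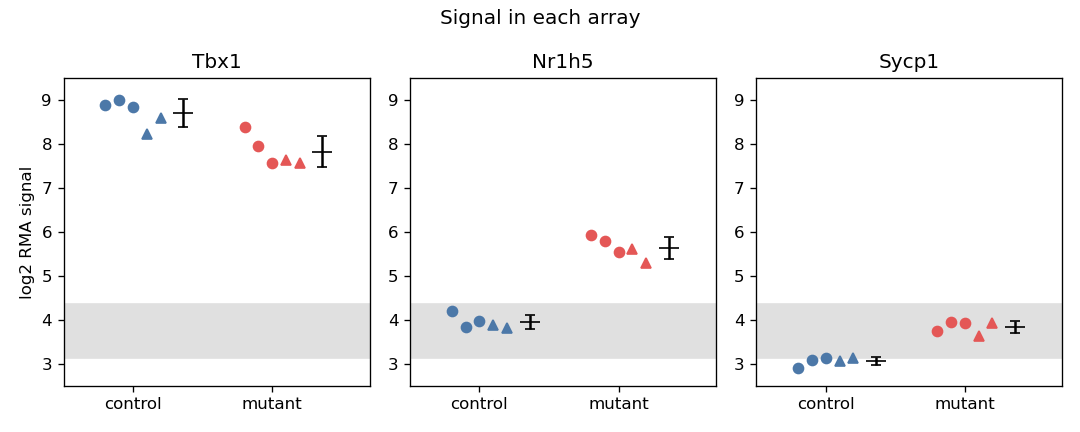
Log2 RMA signal (vertical axis) of Tbx1, Nr1h5 and Sycp1 in each control and mutant array, with circles for arrays numbered 1 to 3, triangles for those numbered 4 and 5, and the group mean ± SD at the right of each group. The grey band is the 3.12 to 4.36 range of Y-linked probe sets in female embryos, and the 5 mutant values of Nr1h5 lie above it.

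At an unadjusted p under 0.05 there were 1559 genes, 938 higher and 621 lower in the mutants, where chance alone gives about 997. Of 100 regroupings of the arrays, the real one included, 10 gave as many, and the highest other gave 2106, so this number does not exceed that of arbitrary groupings. The groups did not overlap for 364 genes (1.83%, against 0.794% by chance), 254 higher and 110 lower. The share by chance is an average, and this count was not made in the regroupings, so whether it exceeds that of arbitrary groupings was not tested. The smallest limma adjusted p after the pair of called genes was 0.253. Of the genes without overlap, those of smallest p in the higher direction all missed the threshold. Ldha, lactate dehydrogenase A, had a log2 difference of 0.33, Pgk1, phosphoglycerate kinase, 0.36, and Pfkfb3, a regulator of glycolysis, 0.40. The values were 0.25 for Kdm3a, 0.48 for Tpmt, 0.50 for Adgrl4, 0.38 for Map9 and 0.34 for Sparcl1. In the lower direction, which also held no gene past the threshold, Col2a1, the main collagen of cartilage, had -0.53, and Bmper, a secreted BMP-binding protein, had -0.45. Rnu7 read 3.54 in the mutants and 4.03 in the controls, with 1 array above the background range, so no difference is given for it. The remaining values were -0.25 for Kctd12, -0.40 for Mir692-1, -0.36 for Fzd4, -0.37 for Slc24a5, -0.27 for Mdfi, -0.34 for Cmtm7 and -0.22 for Psmb4. The standard errors of these log2 differences lay near 0.05 for Ldha, Kctd12 and Psmb4 and reached 0.12 for Col2a1.

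Hypoxia and glycolysis genes were higher in the mutants as a group. The median log2 difference of the 18 measured members was 0.27, 17 of them were higher, and the list mean was higher in the mutant of each of the 5 same-number pairs. Adjusted over the list alone, 10 members rose, and 0 passed over all genes. They included the glycolytic genes Ldha (0.33), Pgk1 (0.36) and Tpi1 (0.28), and the hypoxia-inducible genes Egln3 (0.36), Bnip3 (0.32), P4ha1 (0.36) and Adm (0.36). Vegfa (0.23) and Slc2a1 (0.27) did not pass. The camera adjusted p of the list was 1.15e-13 at the preset correlation, and the adjusted p = 0.285 with an estimated correlation. The fry adjusted p was 0.0798 in the directional test and 0.00153 in the mixed test. An exact permutation test of the list mean gave p = 0.0159, or 0.298 adjusted over the 25 lists. The list mean differed by 0.24 in the arrays numbered 1 to 3 and by 0.23 in those numbered 4 and 5.

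**Figure D2:**
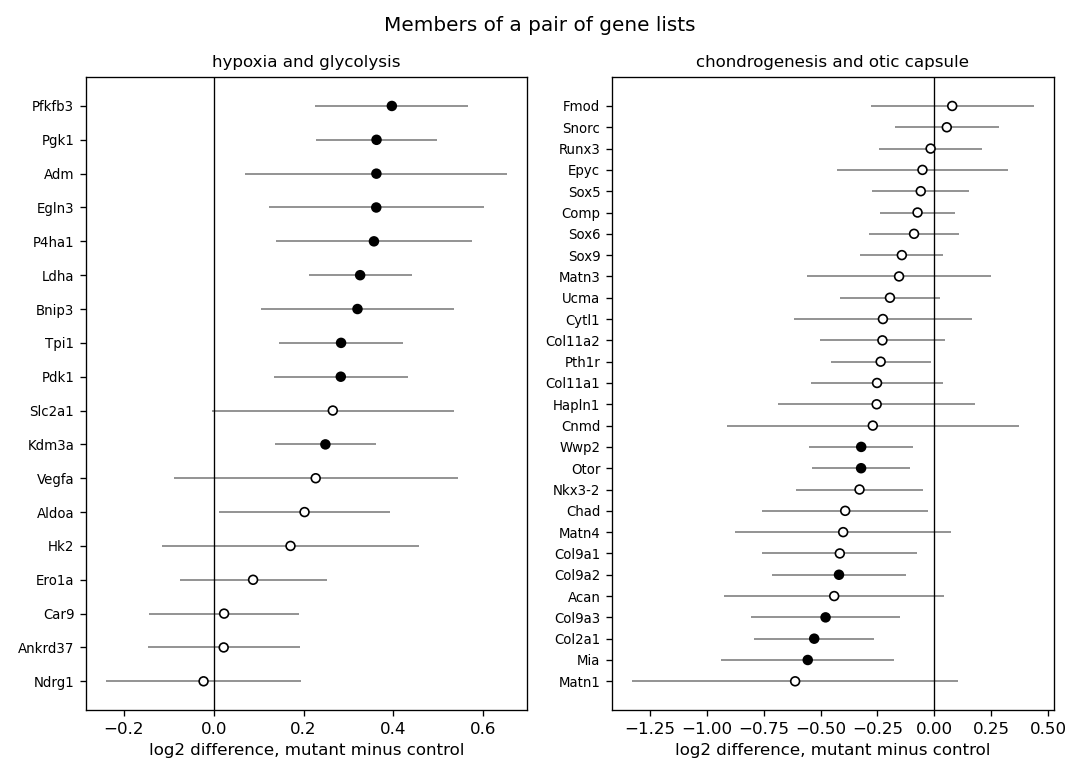
Log2 difference between mutants and controls (horizontal axis) of each measured member of the hypoxia and glycolysis list and of the chondrogenesis and otic capsule list, with 95% intervals as lines and filled points for members that passed adjusted over the list alone. Filled points number 10 in the former list, all above 0, and 6 in the latter, all below 0.

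Cartilage genes were lower in the mutants. The chondrogenesis and otic capsule list had a median log2 difference of -0.25, with 26 of 28 members lower. Adjusted over the list alone, 6 fell: Col2a1 (-0.53), Col9a2 (-0.42) and Col9a3 (-0.48), which encode cartilage collagens, Mia (-0.56), Otor (-0.32) and Wwp2 (-0.32). Over all genes 0 passed. Sox9, the main chondrogenic transcription factor, had -0.14 and did not pass. The camera adjusted p was 4.51e-10, and the adjusted p = 0.670 with an estimated correlation. The exact permutation p of the list mean was 0.0794. The list mean was lower in the mutant of all 5 same-number pairs, with a difference of -0.35 in the arrays numbered 1 to 3 and of -0.13 in those numbered 4 and 5.

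Neuronal genes were higher and muscle genes lower, without any member that passed. For the cochleovestibular ganglion neurons, the sensory neurons of the inner ear, the median log2 difference was 0.32 and 21 of 22 members were higher, among them Neurod4 (0.74) and Elavl4 (0.56). The camera adjusted p was 8.34e-08, the adjusted p = 0.672 with an estimated correlation, and the exact permutation p of the list mean was 0.111. The mean was higher in the mutant of 4 of the 5 same-number pairs. Without mutant 5 the median was 0.20, and without control 2 the difference of the list means went from 0.35 to 0.23. Mutant 5 had the highest mean of this list, 0.78 above the control mean, and of the hindbrain and neural tube list, 0.74 above it. For skeletal myoblasts the median was -0.19 with 23 of 25 lower, among them Myod1 (-0.34). Pax3, also in that list, stood at 0.70. The mean of the myoblast list was higher in the mutant of 1 of the 5 pairs. Its median was -0.09 without control 4, -0.35 without mutant 4 and -0.31 without control 3, and the difference of the list means went from -0.17 to -0.06, -0.29 and -0.26. The camera adjusted p was 0.000228, the adjusted p = 0.672 with an estimated correlation, and the exact permutation p of the list mean was 0.373, or 0.837 adjusted. The preset camera adjusted p was 0.105 without control 4 and 0.111 with the neural lists in the fit. The within-batch differences of the list means were 0.40 and 0.27 for the neurons and -0.13 and -0.23 for the myoblasts, with the arrays numbered 1 to 3 given before those numbered 4 and 5.

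FGF signalling genes were slightly lower, and the retinoic acid list was not lower in most pairs. FGF signalling had a median log2 difference of -0.09 with 19 of 25 members lower, including the feedback inhibitors Spry2 (-0.25) and Spry4 (-0.28), and 0 passed adjusted over the list alone. Its mean was lower in the mutant of all 5 same-number pairs. Its camera adjusted p was 0.00191, the adjusted p = 0.607 with an estimated correlation, and the exact permutation p was 0.0238, or 0.298 adjusted. With the neural lists in the fit the preset camera adjusted p was 0.0746. The within-batch differences were -0.08 and -0.08. Retinoic acid metabolism and response had a median of -0.07 with 16 of 22 lower, including Rxrb (-0.23) and Rxrg (-0.34), and 0 passed adjusted over the list alone. Its mean was higher in the mutant of 3 of the 5 same-number pairs, and the lowest value was that of mutant 5 (-0.27). Without mutant 5 the difference of the list means went from -0.05 to 0.00349 and the median was -0.05, while the means differed by -0.08 without mutant 1 and by -0.03 without control 2. Its camera adjusted p was 0.0318, the adjusted p = 0.672 with an estimated correlation, and the exact permutation p was 0.556, or 0.837 adjusted. The preset call was lost without mutant 3 (0.0842), mutant 5 (0.375), control 1 (0.0616), control 2 (0.0927) or mutants 4 and 5 (0.235), with array weights (0.148), with sex in the fit (0.0694), with the neural lists in the fit (0.802) and in only the arrays numbered 1 to 3 (0.165). The within-batch differences were -0.02 and -0.11. The enzymes that break down retinoic acid were not called: Cyp26a1 had a log2 difference of -0.07 ± 0.16 (SE), Cyp26b1 0.05 ± 0.17 and Cyp26c1 -0.15 ± 0.09. The sign of Cyp26a1 and Cyp26b1 turned when single arrays were left out. Pou3f4, a transcription factor of the periotic mesenchyme, had -0.10 ± 0.13.

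**Figure D3:**
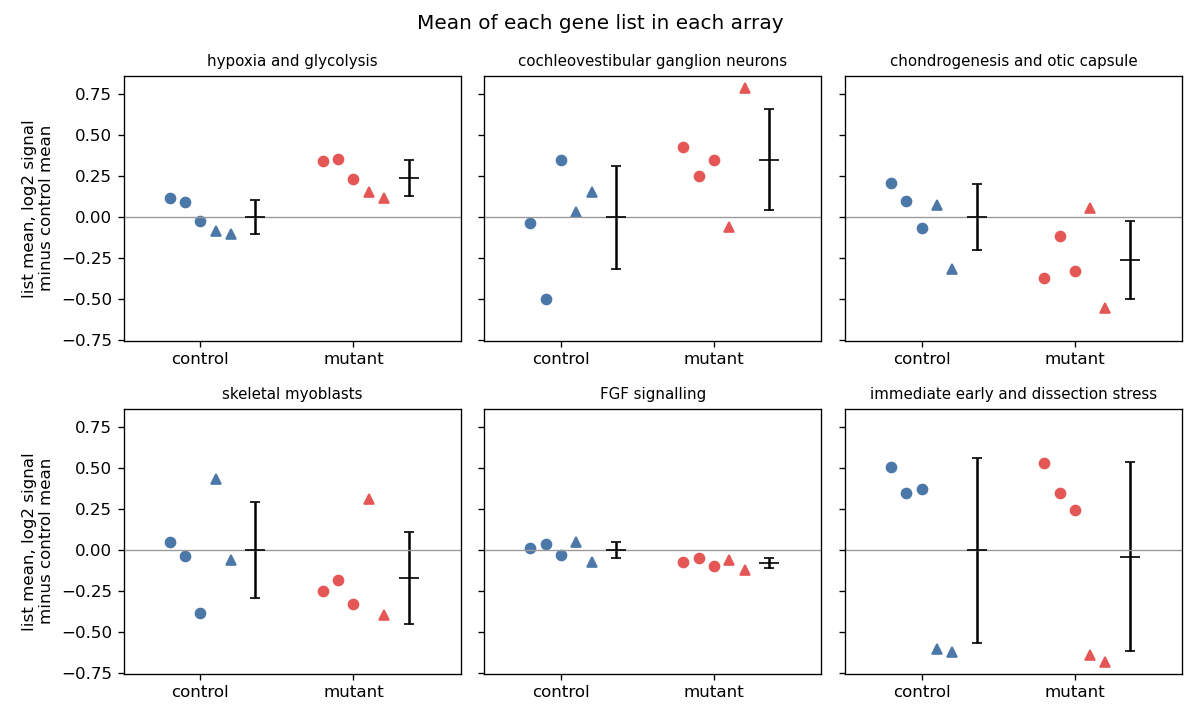
Mean log2 signal of each of 6 gene lists in each array relative to the control mean (vertical axis), with circles for arrays numbered 1 to 3, triangles for those numbered 4 and 5, and the group mean ± SD at the right of each group. The immediate early list lies between 0.24 and 0.53 in arrays numbered 1 to 3 and between -0.68 and -0.60 in those numbered 4 and 5, in mutants and controls.

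Camera at its preset correlation called 6 of the 25 lists, 2 higher and 4 lower. With an estimated correlation, in fry's directional test and in the adjusted permutation tests 0 lists passed. With the replicate number as a block camera called 10 lists, adding red blood cells, WNT signalling, hedgehog signalling and connective tissue. As many as 83 of 100 regroupings of the arrays called at least 6 lists, so the number of called lists does not exceed that of arbitrary groupings.

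The other 19 lists were not called by preset camera. Among tissue lists the median log2 difference and camera adjusted p were -0.09 and 0.204 for periotic mesenchyme, 0.04 and 0.204 for otic sensory and prosensory epithelium, -0.05 and 0.204 for the otic vesicle epithelium, -0.06 and 0.473 for neural crest, 0.06 and 0.331 for blood vessel endothelium, -0.14 and 0.204 for red blood cells, -0.04 and 0.204 for macrophages, 0.04 and 0.246 for hindbrain and neural tube, -0.03 and 0.204 for surface and pharyngeal epithelium, and -0.10 and 0.168 for connective tissue. The mean of the neural crest list was 0.09, opposite in sign to its median. Among pathways they were 0.03 and 0.640 for T-box factors, whose mean was -0.01, -0.000824 and 0.389 for the Tbx1 pathway in pharyngeal mesoderm, -0.06 and 0.204 for Hox genes, -0.01 and 0.204 for BMP and TGF-beta signalling, -0.05 and 0.0553 for WNT signalling and -0.10 and 0.0553 for hedgehog signalling. Cell proliferation had 0.01 and 0.807, p53 targets 0.04 and 0.204, and the immediate early genes -0.04 and 0.518. Adjusted over the list alone, Hey2, a Notch-responsive transcription factor, rose in the sensory list (0.45), Sparcl1 rose in the otic vesicle list (0.34) and Bmper fell in the BMP list (-0.45). Hey2, Sparcl1 and Bmper did not pass over all genes, and adjustment over 1 list takes no account of the other lists. Hey2 differed by 0.65 in the arrays numbered 1 to 3 and by 0.16 (interval -0.14 to 0.45) in those numbered 4 and 5.

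The immediate early genes differed between arrays in a way that both groups shared. Fos read 8.82 to 9.08 in arrays numbered 1 to 3 and 5.49 to 5.91 in those numbered 4 and 5, in both groups. Egr1 read 8.03 to 8.72 against 5.63 to 6.03 and Fosb 8.80 to 9.57 against 5.96 to 6.24. The first principal component held 29.9% of the variance, and mutant 5, whose neural genes such as Gpm6a and En2 were high, stood at 37.0 on it. Whether the place of mutant 5 follows the genotype was not tested. Without mutants 4 and 5 the called genes still numbered 2, and preset camera called 11 lists.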

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

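The tests on the batch, sex and mesenchyme share, the immediate early test and the splits for the hypoxia and cartilage medians and for genes at an unadjusted p under 0.05 were chosen after the results were seen. The splits for genes and lists past the threshold and the tests on neighbouring genes and neural tissue were set before their own results were seen.

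Dixon's rule marked 10 of 188 groups of 5 values as holding an array far from the others, where chance gives about 9, and 5 of the 10 lay in mutant 5. In mutant 5 these were the first principal component (37.02), the mean of the hindbrain and neural tube list (0.7367), the mean of the macrophage list (-0.4348), Pf4 (log2 signal 6.212) and Plk2 (10.63). In mutant 4 they were Hoxb7 (6.42) and Sp5 (6.283). The others were Mir692-1 in mutant 1 (9.205), Sycp1 in control 1 (2.901) and Kdm3a in control 5 (9.369). In data outside the gene comparison, the probe set 10500796, which the annotation does not name, was higher in the mutants, at 5.57 ± 0.26 against 4.41 ± 0.14 (SD, n = 5 each), a measured log2 difference of 1.156 with a limma adjusted p of 0.0205 over all probe sets. Of its controls 3 read above the background of 4.36, and with the others set to it the mean signal was 2.18-fold higher in the mutants, an estimate without an interval.

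Of 100 splits of the arrays into groups of 5, 2 gave 2 or more genes past the threshold, the real split included. That is under the bound of 5 of 100 set for it, but these splits ignore the same-number pairs. The real split gave 2 and the highest other 6. That other split set 5 of the 6 arrays numbered 1 to 3 against the rest, and so follows the array batch. Among the 16 splits that part all 5 same-number pairs, the highest other count was 0, but 16 are too few for a share under 0.05. The free splits thus argue against arbitrary grouping for the count of genes, while with the pairs kept it cannot be excluded. For the 1559 genes at an unadjusted p under 0.05, 10 of the 100 splits gave as many, with a highest other of 2106, so chance cannot be excluded for that number. For lists, 83 of the 100 splits called at least the 6 of the real split, with a highest other of 19, so chance cannot be excluded for the number of lists. Arrays that vary together in cell makeup, which preset camera does not model, may give such counts.

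Nr1h5 and Sycp1 are neighbours among the measured genes and both read higher in the mutants. The array batch is argued against by the design, since each batch holds the same replicate numbers of both groups. With Nr1h5 values under background set to it, the lower interval bounds of the log2 difference within each batch were at least 0.754. Nr1h5 was picked from these same arrays, so those bounds are not independent evidence. Sex is argued against by the lower bound of 1.07 with sex in the fit. These bounds use the standard errors of the values as measured. A difference over a longer stretch stays open: of the 10 nearest measured genes, 2 (Tspan2, 0.29, and Sike1, 0.22) had an unadjusted p under 0.05. The unnamed probe set 10500796, also higher in the mutants, was not part of this test, since its place in the genome is not given in the sources used here. Its number is close to those of Nr1h5 (10500780) and Sycp1 (10500754). Whether probe set numbers follow the gene order was not checked, so it may lie in the same stretch. A strain difference between the embryos may give such a stretch. The labels name T-Cre in both groups, and neither gene is among the nearest measured genes around Tbx1. The strain of the embryos is not given in the sources used here, so a strain difference and an effect of Tbx1 loss cannot be told apart.

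The hypoxia and glycolysis list was higher in the mutants. Among 100 splits only the real one, 1 split, gave a median as large as 0.27, with a highest other of 0.2525. Among the 16 splits that part all 5 pairs the highest other was 0.1718, but 16 are too few for a share under 0.05. The split test was chosen after this list had stood out, and it takes no account of the other lists tested. The exact permutation p of the list mean was 0.0159, or 0.298 adjusted over all lists tested, so chance cannot be excluded for this list. More neural tissue in some mutants is argued against, since 125% of the median was kept with the neural lists in the fit. The array batch is argued against, since each batch holds the same replicate numbers of both groups. Within each batch the lowest mutant list mean also lay at least 0.113 above the highest control. Early response during dissection is argued against as the whole source by the immediate early list itself, which differed between the groups by -0.0395 (95% interval -0.174 to 0.095) with the batch in the fit. With the immediate early list in the fit 103% of the median was kept. With the batch added, the hypoxia list mean still differed by 0.253 (0.177 to 0.329). Since the immediate early list barely differed between the groups, these fits could hardly have removed the difference and are no further evidence. Across arrays the list did follow the immediate early list once group means were removed (permutation p = 0.00861), which had been named as the sign of this source, was met, and was set aside only after it was seen, since with group means removed it does not bear on their difference. Handling that leaves the immediate early genes unmoved was not tested, so an effect of Tbx1 loss on this list stays a hypothesis.

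The cartilage list was lower in the mutants, and no explanation was excluded, chance included: 10 of 100 splits gave a median as large in size as 0.25, with a highest other of 0.4158, though the list mean was lower in the mutant of all 5 same-number pairs (the 16 splits that part all 5 pairs, with a highest other of 0.2646, are too few for a share under 0.05). A lower share of mesenchyme stays open: the periotic mesenchyme list without shared genes differed by -0.03 and the cartilage list by -0.26, but the difference of -0.23 between them had an exact permutation p of 0.143, which decides neither way. More neural tissue in some mutants stays open too, since 50.2% of the median was kept with the neural lists in the fit. The median of -0.25 then became -0.13, so the mutants' tissue makeup and a lower expression in cartilage cells cannot be told apart.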

How the results depend on the processing

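Of 66 named genes besides Tbx1, 59 kept direction and side of the threshold under each of the 22 or 23 alternatives run for them, which leave out those that give only a count (fold threshold, treat, all probe sets). These 59 were all genes that missed the threshold, so their staying on that side of it says little. Of the called genes, Nr1h5 kept its call in 21 of 22 alternatives and Sycp1 in 20 of 22. The genes past the threshold numbered 2 in the chosen model and in every fit without 1 array. They numbered 0 among probe sets at or above the median mean signal, which removes both genes, 1 with treat against a fold of 1.2, and, with fewer arrays, 1 in only the arrays numbered 1 to 3 and 0 in only the arrays numbered 4 and 5. The gene lists past the threshold numbered 6 in the main test and 5 to 11 without 1 array, with 11 without mutant 2, 10 without mutant 4 and 9 without control 3. They numbered 10 with the replicate block, 16 in only the arrays numbered 4 and 5, 11 without mutants 4 and 5, and 0 with the correlation estimated per list, in fry's directional test and by exact permutation of list means, while fry's mixed test gave 1. The block changed no call of a named gene. For these counts the cause was not tested. Tbx1 lay between -1.03 and -0.81 without 1 array and was never called. Robust eBayes was not run for the lists. Fits by batch, without mutants 4 and 5, with the neural lists and by permutation were added after seeing the data.

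The sign turned for genes that were not called, and the cause was not tested. Cyp26a1 (-0.07) became 0.0534 with array weights, 0.0265 without mutant 5, 0.0104 without control 1, 0.0176 without control 2, 0.107 in only the arrays numbered 4 and 5, 0.056 without mutants 4 and 5 and 0.118 with the neural lists, and ranged from -0.174 to 0.0265 without 1 array. Cyp26b1 (0.05) became -0.106 without mutant 5, -0.00509 without control 5 and -0.148 with the neural lists, and ranged from -0.106 to 0.197 without 1 array. In only the arrays numbered 4 and 5 Fgf20 became 0.0155 and Pou3f4 0.256, and Klf2 became 0.0122 without mutants 4 and 5. Signal near background limits Sycp1, Rnu7 and the controls of Nr1h5.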

Other observations

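All 4 gene lists in this part were put together after the main results had been seen. Further glycolysis genes and cholesterol synthesis genes were picked after some of their members had been seen to be higher, so their counts are not independent evidence, and the lens list after crystallins had been seen among the genes that part the arrays. The test of the further glycolysis genes and its bound were likewise set after some members had been seen. No value of the oxidative phosphorylation list had been looked at when its test was set.

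Oxidative phosphorylation genes, which encode subunits of the mitochondrial respiratory chain and ATP synthase, were lower in the mutants, with a median log2 difference of -0.08 and 63 of 72 lower. Their mean was lower in the mutant of all 5 same-number pairs, and the exact permutation p was 0.0238, or 0.0476 adjusted over these 4 lists and 0.0714 without the further glycolysis list, which was picked from members seen to be higher. Adjusted over the list alone, 0 genes passed, and 4 of 100 splits gave a median as large. Among the 16 splits that part all 5 pairs, 2 gave a median as large in size, the real split included, with a highest other of 0.08309. A general rise of energy metabolism genes as the source of the higher hypoxia and glycolysis list is argued against by that median of -0.081.

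Of 18 further glycolysis genes 14 were higher, with a median of 0.119, and 5 rose adjusted over the list alone: Slc16a3 (0.49), a lactate exporter, Pfkl (0.36), Pfkp (0.37), Pgm1 (0.29) and Pkm (0.19). Ldhb had -0.19 and did not pass. The exact permutation p was 0.00794, the smallest it can be, or 0.0317 adjusted. A wider rise of glycolytic enzymes may be present, but 6 of 100 splits gave a median as large, which misses the bound of under 5 set for it, so the question stays open. Cholesterol synthesis genes had a median of 0.17 with 14 of 19 higher, and Msmo1 (0.30) and Nsdhl (0.35) rose adjusted over the list alone. Their exact permutation p was 0.0556, or 0.0741 adjusted.

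Lens genes stood apart in 1 array. In mutant 1 the lens crystallin gene Cryaa read 11.2 and the mean of 18 lens genes lay 1.22 above the control mean, while in the other 9 arrays Cryaa read 5.54 to 5.97. The exact permutation p of the lens list between the groups was 0.825.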
